A study of Mus musculus with 18 samples.

How the data were processed

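Total RNA of dorsal skin from 18 mice (NT, TS and TS_WB, 6 arrays each) was extracted with Isogen, purified on RNeasy columns, labelled from 100 ng and hybridised to Affymetrix mouse genome arrays, per the labels' protocols. The deposited table holds 1 value per probe set and array; the method of summarising and normalizing them is not given in the sources used here. The deposited values range from 2.93 to 19.04 with array medians near 6.9, so they were read as log2 values; the base of the logarithm is not stated, and folds rest on it. The table holds no measure of background, so the size of a difference is uncertain for a gene whose lower group mean lies under the array median. Array medians averaged 6.94 in NT, 6.94 in TS and 6.90 in TS_WB. Scanner files were not used here.

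Of 45101 probe sets, the 64 Affymetrix control probe sets were left out and 45037 tested. Of these, 33091 (73.5%) ranged by less than 0.01 over all 18 arrays, 7527 of them identical to the last digit, so only 11946 carry a measured difference; the table's origin of these constant values is not given in the sources used here. The probe set of Hr, the gene named for the hairless phenotype, is among them and gives no information. Tiny differences of such probe sets can pass the test, and counts are therefore given with and without a minimum difference of 0.01, chosen after seeing the data. Gene symbols come from the platform annotation supplied with the table, in which 34957 tested probe sets have 1 symbol, 920 several and 9160 none; none was named from a probe set with several. Il36g and Il36b appear there as Il1f9 and Il1f8. A gene was represented by its probe set with the highest mean over all arrays, which gave 18201 genes, 6843 of them with a range of at least 0.01.

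Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 18 arrays in 1 fit, no covariate), with Benjamini-Hochberg adjustment over the 45037 probe sets per comparison and a threshold of adjusted p under 0.05. Every adjusted p of a gene or probe set is from this fit unless an alternative is named. A gene was said to rise or fall only if it passed and differed by at least 0.01. The 32 gene lists, covering epidermal programmes, lipids, cell cycle, immune and other cell types, matrix, stress and clock genes, the tests, the rule for naming genes, the splits and the alternatives were fixed before the data were examined, except where a choice is said to be later. They were tested with camera at a preset correlation of 0.01, against all other genes, adjusted over the 32 lists, and again with a correlation estimated per list and with fry, which asks whether a list's genes move on balance in 1 direction. Fry called 29, 28 and 23 lists in TS against NT, TS_WB against TS and TS_WB against NT. Medians of lists are over varying members. Counts of rises and falls are out of a list's genes on the array, and the constant ones among them give no information. In some lists few members vary: 6 of 27 T cell genes, 5 of 17 B and plasma cell genes and 11 of 25 endothelial genes. In the matrix-degrading enzyme list of TS against NT the median (-0.15) and mean (-0.03) lie below 0 while the test points up, without a call. In TS_WB against TS, cholesterol synthesis has a median of 0.30 and a mean of -0.37, the junction list 0.44 and -0.04, the nerve list 0.24 and -0.08, and the B and plasma cell list -0.01 and 0.07. There the interferon list (median and mean 0.07) and the melanocyte list (0.32 and 0.02) lie above 0 while the test points down. In TS_WB against NT, median and mean differ in sign for basal keratinocytes (0.14 and -0.42), ceramides (-0.11 and 0.08) and the clock (-0.24 and 0.05), and the nerve list (-0.13 and -0.47) lies below 0 while the test points up. Camera called none of these lists on the deposited values. In TS_WB against TS fry called cholesterol synthesis (adjusted p = 0.000524) and melanocytes (0.00809) down, and junctions (0.00254) and nerve (0.0102) up. It called none of the others.

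Genes named were chosen by this rule: per comparison the 10 largest rises and 10 largest falls that passed, leaving out clone and model names and antigen receptor segments; the 4 members with the smallest p of each shifted list; and 21 fixed epidermal and inflammatory genes. Alb, the outlying liver genes and several genes of the last paragraphs (Dbp, Per3, Tef, Arntl, Mt4 and Defb3) were chosen after their values were seen. Of the genes that the rule gives, a part is printed, and the counts cover them all. Array measures (medians, control probe sets, marker means) were compared by exact permutation of 6 against 6 arrays, two-sided, whose smallest p is 0.00216, and adjusted by Benjamini-Hochberg. The pair of comparisons that shares the TS arrays was set against 100 simulated data sets of unchanged groups and against 20 splits of the TS arrays.

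The fit was tested on simulated data for TS against NT with 45037 probe sets: of 100 probe sets changed by 0.5 log2 it recovered 60, of 100 changed by 1 log2 it recovered 92, and it called 4 unchanged ones. The list test on 18201 genes recovered the 1 shifted list of 32 and called 0 others. That simulated result does not measure false list calls in the data, where genes of some lists move together. The correlation estimated per list ranged there from -0.06 (red blood cells) to 0.53 (cell cycle). Another split of the NT and TS arrays also gave 22 shifted lists. Replicates were checked for duplicates; the smallest mean absolute difference between arrays of a group was 0.141 in NT, 0.144 in TS and 0.151 in TS_WB, so none were merged. The labels call the replicates biological, but which animals shared a cage or a day is not given in the sources used here, and p-values measure the spread between these samples. The number of arrays limits the precision. All columns of the table belong to 1 of the 18 samples.

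Alternatives tried were the replicate number as a block, quantile normalization, median centring, a filter on dim probe sets, a trended robust prior, array quality weights, fits of the 12 arrays compared, leaving out each array, a minimum of 1.5-fold, adjusted p thresholds of 0.01 and 0.1, the mean of a gene's probe sets, and the list tests above. Counts restricted to varying probe sets or genes, or to differences of at least 0.01, were added after seeing the data. Pseudocounts of 1 and 64 were planned for linear values and not run, since the values are logarithmic. Camera sets a list against all other genes, most of which are constant, and scaling shifts those constant genes. List calls gained or lost after quantile normalization or median centring are therefore given but not read as shifts.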

Results

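Transcript levels were measured in dorsal skin of male HR-1 mice, an albino hairless strain, on Affymetrix mouse genome arrays. The 18 arrays fall into 3 groups of 6. NT mice were not stripped. TS mice had cellophane tape applied and removed 3 times per week for 4 weeks, each session ending at a transepidermal water loss of 70 to 100 g/m2/h. Tape stripping removes the outer layers of the stratum corneum and so disrupts the skin barrier. TS_WB mice were stripped in the same way and also received winged bean extract by mouth, at 200 mg/kg/day in 0.3% carboxymethylcellulose, 5 times per week for 5 weeks. Values are on the deposited log2 scale throughout, and ± gives the SD over 6 arrays unless SE is named.

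Arrays of a group correlated with each other over probe sets at r of 0.901 to 0.989 in NT, 0.957 to 0.986 in TS and 0.951 to 0.990 in TS_WB. Between NT and TS arrays r was 0.838 to 0.939, and between TS and TS_WB arrays it was 0.585 to 0.685. The array carries control probe sets for the 5' and 3' ends of beta-actin and Gapdh, whose difference shows how far labelled RNA extends from the 3' end. The 3' minus 5' difference for beta-actin was -0.51 ± 0.10 in NT (n = 6), 0.16 ± 0.07 in TS (n = 6) and 5.69 ± 0.25 in TS_WB (n = 6). For Gapdh it was -0.59 ± 0.11, -0.44 ± 0.12 and 3.70 ± 0.36. The TS_WB values differed from those of TS in both (exact permutation test, two-sided, p = 0.00216 for each, the smallest p that 6 against 6 arrays allow, adjusted over the array measures, 0.00333). The actin difference between TS and NT, 0.66, also passed this exact test (p = 0.00216), while that of Gapdh, 0.15, did not pass after adjustment (exact permutation p = 0.0476, adjusted 0.0866). On the array NT 5, albumin (Alb) stood at 19.04, while the mean over TS arrays was 6.42 ± 0.20; all 13 values above 16 in the table were on NT 5.

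**Figure D1:**
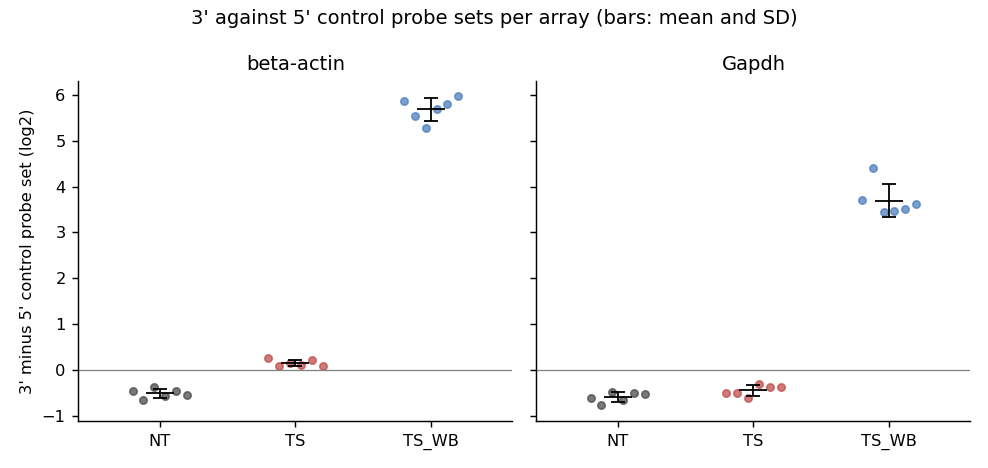
Difference between the 3' and 5' control probe sets of beta-actin and Gapdh (log2) for each of the 18 arrays, by group; points are arrays, bars the mean and SD of 6. The TS_WB arrays average 5.69 for beta-actin and 3.70 for Gapdh, above every NT and TS array.

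The comparison of TS with NT asked what repeated stripping did to the skin. Stripped skin had much higher transcript levels of Rptn, Krt6b and several Sprr genes and far lower levels of Krt77. Rptn, which encodes the cornified envelope protein repetin, rose from 5.09 ± 0.62 to 13.28 ± 0.51 (n = 6 per group, adjusted p = 2.6e-10). Krt6b, a keratin induced in wounded and hyperproliferative epidermis, rose from 7.56 ± 0.88 to 14.49 ± 0.60 (122-fold, adjusted p = 9.2e-08). Krt77, a keratin of the upper epidermis and sweat duct, fell from 15.10 ± 0.23 to 6.51 ± 0.48 (adjusted p = 1.6e-12). The lower means of Rptn and Krt77 lie below the median of the arrays (6.94), so no fold is given. In stripped skin 30 of 41 skeletal muscle genes and 15 of 24 adipocyte genes also fell, including parvalbumin (Pvalb), which fell by 3.86 (SE 0.36), and adiponectin (Adipoq), which fell by 2.19 (SE 0.26).

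**Figure D2:**
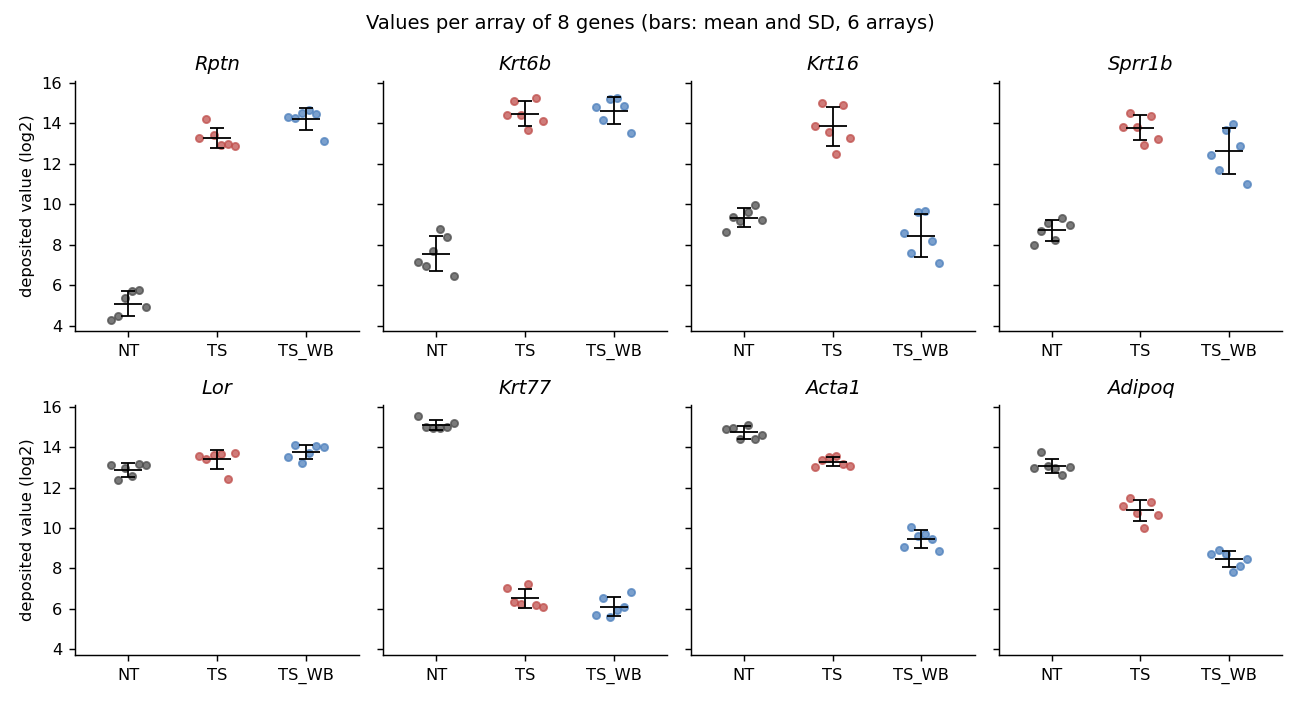
Deposited log2 values of 8 genes on each array of NT, TS and TS_WB; points are arrays, bars the mean and SD of 6. Rptn averages 5.09 in NT and 13.28 in TS, Krt77 averages 15.10 and 6.51, and Krt16 averages 13.86 in TS and 8.46 in TS_WB.

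The largest rises after Rptn and Krt6b were those of the serpin Serpinb12 (5.24, SE 0.32), the envelope precursors Sprr1b (5.09, SE 0.46), Sprr2d (4.63, SE 0.35) and Sprr2h (4.48, SE 0.45), the kallikrein Klk13 (4.90, SE 0.33), the wound keratin Krt16 (4.52, SE 0.50), the stefin Stfa2l1 (4.27, SE 0.35) and the protease inhibitor Wfdc12 (4.24, SE 0.22). The largest falls after Krt77 were those of Jchain, the joining chain of polymeric immunoglobulins (-4.91, SE 0.56), the fast-fibre actinin Actn3 (-4.69, SE 0.63), the lipogenic factor Thrsp (-4.15, SE 0.43), the chemokine Cxcl3 (-4.07, SE 0.45), Pvalb, the kinase Mylk4 (-3.54, SE 0.47), the interferon-inducible Ifi27l2a (-3.31, SE 0.37), the muscle calcium store protein Casq1 (-3.26, SE 0.25) and the dehydrogenase Adh6a (-2.93, SE 0.35). Of the 113 genes named by the rule in this comparison, 103 passed the test; most were chosen by size or p.

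In the list of hyperproliferative and stress-induced epidermis, 17 of 30 genes on the array rose and none fell (21 and 1 adjusted over the list alone, median of varying members 1.93, adjusted p = 2.0e-15). It included Krt6a (1.41, SE 0.30), the growth factor Ereg (4.05, SE 0.26), Stfa3 (2.74, SE 0.20) and interleukin 36 gamma, listed as Il1f9 (1.75, SE 0.16). The call held with an estimated correlation (adjusted p = 0.0313). S100a8 and S100a9, which encode the calprotectin subunits, differed by 1.93 (SE 0.81) and 1.58 (SE 0.82) and did not pass (adjusted p = 0.140 and 0.259). S100a8 passed without NT 4 (adjusted p = 0.0183) and among varying probe sets alone (0.0496).

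Among late differentiation and cornified envelope genes, 22 of 42 rose and 4 fell (29 and 5 adjusted over the list alone, median 0.56, adjusted p = 3.2e-09). The list was not called at adjusted p = 0.137 with an estimated correlation. Rises included the caspase Casp14 (2.35, SE 0.23), transglutaminase Tgm1 (1.23, SE 0.11), Krt1 (1.34, SE 0.17), Krt10 (0.55, SE 0.09) and filaggrin (Flg, 1.05, SE 0.16). Involucrin (Ivl) rose by 0.49 (SE 0.12), and loricrin (Lor) differed by 0.51 (SE 0.23) without passing (adjusted p = 0.169, but 0.0358 with array quality weights and 0.0148 without TS 5). Desquamation proteases and inhibitors, which control the shedding of corneocytes, held 13 of 28 that rose and none that fell (15 and 1 adjusted over the list alone, adjusted p = 8.6e-09), among them Klk9 (1.81, SE 0.15) and Klk7 (0.23, SE 0.05), and kept their call at adjusted p = 0.0343 with an estimated correlation.

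Of 18 basal keratinocyte genes 9 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 9.1e-05, adjusted p = 0.150 with an estimated correlation), including the anchoring collagen Col7a1 (1.24, SE 0.14), Krt14 (0.70, SE 0.18) and the integrin Itga6 (0.75, SE 0.12). Krt5 differed by 0.70 (SE 0.23) and missed the threshold (adjusted p = 0.0533); it passed after quantile normalization (adjusted p = 0.0433), with the filter on dim probe sets (0.0404), with array weights (0.0185), in a fit of the 12 arrays alone (0.0171) and among varying probe sets alone (0.0159). It also passed without TS 4 (adjusted p = 0.0320), TS_WB 3 (0.0243) or TS_WB 6 (0.0224). Epidermal junction genes, such as the desmocollin Dsc1 (2.39, SE 0.17) and plakophilin Pkp1 (0.51, SE 0.08), held 13 of 28 that rose and 3 that fell (the same numbers adjusted over the list alone, adjusted p = 0.0118, adjusted p = 0.217 with an estimated correlation). In ceramides and barrier lipids 14 of 32 rose and 2 fell (14 and 3 adjusted over the list alone, adjusted p = 6.3e-06, adjusted p = 0.0771 with an estimated correlation), among them ceramide synthase Cers3 (1.99, SE 0.19) and the lipoxygenase Alox12b (0.75, SE 0.12). In cholesterol synthesis 9 of 20 rose and none fell (10 and 0 adjusted over the list alone, adjusted p = 8.1e-06, adjusted p = 0.137 with an estimated correlation), with squalene epoxidase Sqle at 0.98 (SE 0.15).

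Cell cycle genes held 24 of 49 that rose and none that fell (35 and 0 adjusted over the list alone, median 0.59, adjusted p = 2.5e-11), including Cdca8 (1.52, SE 0.27) and the mitotic kinase Cdk1 (0.84, SE 0.18). That call was lost at adjusted p = 0.178 with an estimated correlation. Mki67, the proliferation marker, rose by 0.84 (SE 0.24, adjusted p = 0.0255), but not without NT 4 (0.0541), NT 6 (0.0516), TS 1 (0.0587), TS 2 (0.0625) or TS 5 (0.0577). Of 18 mast cell genes 7 rose and none fell (the same adjusted over the list alone, adjusted p = 0.00165, adjusted p = 0.150 with an estimated correlation). The tryptase Tpsab1 (2.44, SE 0.40) and the IgE receptor chain Fcer1a (1.48, SE 0.13) rose. Of 32 immediate early and heat shock genes 9 rose and 2 fell (11 and 3 adjusted over the list alone, adjusted p = 0.00324, adjusted p = 0.211 with an estimated correlation). Junb (0.81, SE 0.17) and the chaperone Hspa1b (0.67, SE 0.13) rose. This call was also lost after quantile normalization (adjusted p = 0.155) and median centring (0.126).

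Skeletal muscle genes held 30 of 41 that fell and none that rose (34 and 0 adjusted over the list alone, median -1.52, adjusted p = 3.1e-20, adjusted p = 0.0691 with an estimated correlation). They included troponin Tnnc2 (-1.59, SE 0.17) and Casq1. Of 24 adipocyte genes 15 fell and none rose (16 and 0 adjusted over the list alone, median -0.85, adjusted p = 3.3e-11), including leptin (Lep, -2.09, SE 0.22) and lipoprotein lipase (Lpl, -0.94, SE 0.11), and the call held at adjusted p = 0.0313 with an estimated correlation. Of 51 hair follicle genes 30 fell and 1 rose (32 and 1 adjusted over the list alone, median -1.24, adjusted p = 3.2e-09, adjusted p = 0.137 with an estimated correlation). The inner root sheath keratin Krt27 (-2.84, SE 0.57) and the bulge marker Cd34 (-1.48, SE 0.15) fell. In the sebaceous gland and fatty acid synthesis list 10 of 32 fell and none rose (the same adjusted over the list alone, adjusted p = 0.00257, adjusted p = 0.255 with an estimated correlation), among them fatty acid synthase Fasn (-1.05, SE 0.19). Liver also expresses some of these lipid genes, and the mean of the varying liver marker genes was 11.42 on NT 5 against a TS mean of 7.85 ± 0.06. The sebaceous list kept its call without NT 5, and the fall of Fasn still passed. Beside these falls, the actin 3' minus 5' difference was 0.66 higher in TS than in NT.

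**Figure D3:**
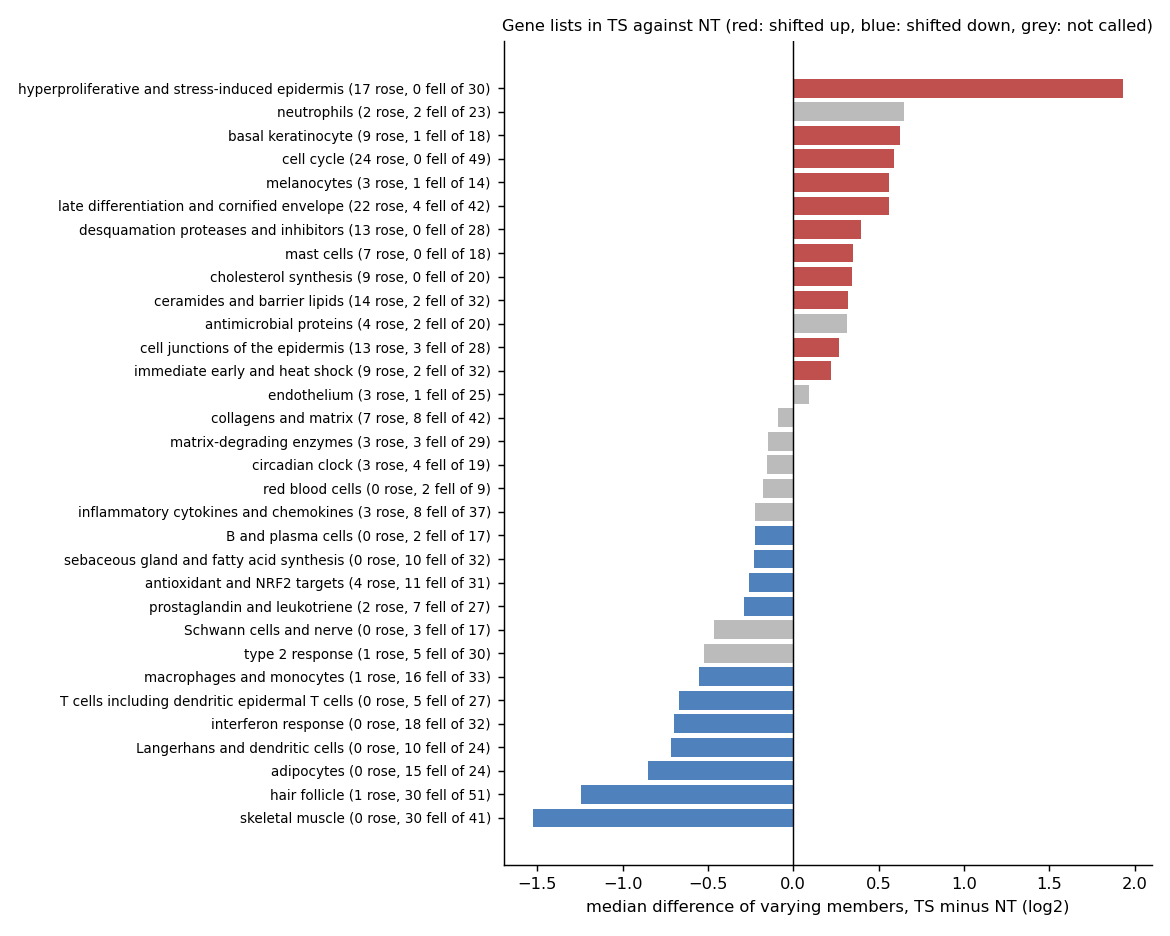
Median difference (TS minus NT, log2) of the varying members of each of the 32 gene lists, with the numbers that rose and fell of those on the array; red bars are lists shifted up, blue bars lists shifted down and grey bars lists not called. Hyperproliferative epidermis has the highest median, 1.93, and skeletal muscle the lowest, -1.52.

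Among immune lists 5 shifted down, mast cells shifted up and 4 were not called by camera. Of the latter, fry called the type 2 list down (adjusted p = 0.00320) and antimicrobial proteins up (0.000101). The falls given next also stood beside an actin 3' minus 5' difference 0.66 higher in TS than in NT. Of 32 interferon response genes, of which 19 varied, 18 fell and none rose (the same adjusted over the list alone, median -0.70, adjusted p = 4.5e-11, adjusted p = 0.0377 with an estimated correlation). The GTPase Gbp2 (-1.53, SE 0.27) and Ifi27 (-0.88, SE 0.14) were among them. Of 24 Langerhans and dendritic cell genes 10 fell and none rose (11 and 0 adjusted over the list alone, median -0.72, adjusted p = 6.7e-07, adjusted p = 0.0313 with an estimated correlation). The lectins Mgl2 (-1.84, SE 0.23) and Cd209a (-1.51, SE 0.16) fell. Cd207, the Langerhans cell marker langerin, differed by -0.46 (SE 0.20) and did not pass (adjusted p = 0.146). Of 33 macrophage genes 16 fell and 1 rose (19 and 1 adjusted over the list alone, adjusted p = 4.1e-09, adjusted p = 0.134 with an estimated correlation). Falls included the lectin Clec4e (-2.88, SE 0.23) and Aif1 (-1.08, SE 0.18). Of 27 T cell genes, of which 6 varied, 5 fell and none rose (the same adjusted over the list alone, adjusted p = 0.000299, adjusted p = 0.0205 with an estimated correlation), with Cd3g at -1.23 (SE 0.18). The T cell call was lost after quantile normalization (adjusted p = 0.166) and median centring (0.158).

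Of 17 B and plasma cell genes, of which 5 varied, 2 fell, Jchain and Ighm (-1.78, SE 0.25), and none rose (the same adjusted over the list alone, adjusted p = 0.0356, adjusted p = 0.0771 with an estimated correlation). That list was not called without NT 3 (adjusted p = 0.0906), TS 1 (0.0669) or TS 3 (0.0511), after median centring (0.128) or with the mean of a gene's probe sets (0.0546). In antioxidant and NRF2 targets 11 of 31 fell and 4 rose (14 and 4 adjusted over the list alone, adjusted p = 0.00612, adjusted p = 0.0771 with an estimated correlation). The glutathione transferase Gstm2 fell by 1.17 (SE 0.08). In prostaglandin and leukotriene genes 7 of 27 fell and 2 rose (8 and 2 adjusted over the list alone, adjusted p = 0.0259, adjusted p = 0.0771 with an estimated correlation). The prostaglandin E receptor Ptger3 fell by 2.36 (SE 0.13). The prostaglandin call was lost with the mean of a gene's probe sets (adjusted p = 0.0521) and among varying genes alone (0.0635). Inflammatory cytokines and chemokines were not called (3 rose and 8 fell of 37, 4 and 8 adjusted over the list alone, adjusted p = 0.214); Il1b differed by -0.50 (SE 0.27, adjusted p = 0.275, but 0.0203 without TS 5). Camera did not call the type 2 list either (1 rose and 5 fell of 30, 2 and 7 adjusted over the list alone, adjusted p = 0.264, but 0.0497 after quantile normalization), while fry called it down (adjusted p = 0.00320). Tslp, an epithelial cytokine, fell by 0.85 (SE 0.21).

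In all, 7020 of 45037 probe sets passed at adjusted p under 0.05, 3437 higher and 3583 lower in TS. Of these, 4551 differed by at least 0.01, 2238 higher and 2313 lower; the remaining 2469 differed only at the level of rounding. At least 1.5-fold was reached by 1417, of which 576 were higher and 841 lower. Without NT 5 the count was 6494, and in a fit of the 12 NT and TS arrays alone it was 6621. Of the 32 lists 11 shifted up and 11 down, and 6 of the 22 were called with an estimated correlation.

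The comparison of TS_WB with TS asked what the oral extract did in stripped skin. On TS_WB arrays the wound keratins Krt16 and Krt6a and 27 of 41 skeletal muscle genes fell, beside an actin 3' minus 5' control difference of 5.69 against 0.16 in TS. Krt16 fell from 13.86 ± 0.96 to 8.46 ± 1.06 (42.3-fold, n = 6 per group, adjusted p = 1.4e-07), and Krt6a fell by 2.34 (SE 0.30). Krt6b did not pass (0.15, SE 0.42, adjusted p = 0.945). Uqcrh, a subunit of respiratory complex III, fell from 13.11 ± 0.14 to 5.24 ± 0.08 (adjusted p = 1.6e-21). The hair keratin-associated protein gene Krtap6-5 rose from 6.55 ± 2.04 to 10.08 ± 0.58 (adjusted p = 0.000706). The lower means of Uqcrh and Krtap6-5 lie below the median of their arrays (6.90 and 6.94).

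The other large falls were those of the galectin Lgals7 (-6.97, SE 0.63), the ATP synthase subunits Atp5l (-6.84, SE 0.05) and Atp5e (-6.27, SE 0.08), the prefoldin Pfdn5 (-6.36, SE 0.06), the translocon protein Ssr4 (-6.36, SE 0.15), troponin Tnni2 (-6.29, SE 0.22), the keratinocyte surface protein Ly6d (-6.29, SE 0.13), the ribosomal protein Rps9 (-6.02, SE 0.04) and Fxyd3 (-5.95, SE 0.08). Another probe set of Rps9 changed by 0.65 and another of Tnni2 by 0.47, both upward. The other large rises were those of Rpl27a (4.20, SE 0.37), the ribosome assembly factor Rpf2 (3.92, SE 0.07), Krtap16-3 (3.25, SE 0.84), the GTPase Rab32 (3.13, SE 0.66), AY036118 (3.04, SE 0.07), the matrix regulator Ccn2 (2.91, SE 0.39), Krt27 (2.80, SE 0.57), Fam107a (2.72, SE 0.42) and Prr9 (2.68, SE 0.51). Further probe sets of Rpf2 changed by 0.99 and -0.91. The other varying probe sets of Rpl27a, Fam107a and Krtap16-3 changed by 0.06, 0.34 and 2.26. Of 75 named genes 66 passed, and of the 18 with other varying probe sets 4 had such a set that passed in the opposite direction.

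Probe sets of the same gene, which lie at different places along its transcript, were correlated closely in TS against NT and weakly in TS_WB against TS. Over 1502 genes with 2 varying probe sets, the correlation of their differences was 0.80 in TS against NT (95% bootstrap interval 0.756 to 0.843) and 0.224 in TS_WB against TS (0.158 to 0.288). These are correlations across genes, which are not independent replicates. Where both probe sets passed, their signs were opposite in 14 of 414 genes (3.38%) in TS against NT and in 555 of 1250 genes (44.4%) in TS_WB against TS. A direction for a gene in TS_WB therefore holds for the probe set used.

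**Figure D4:**
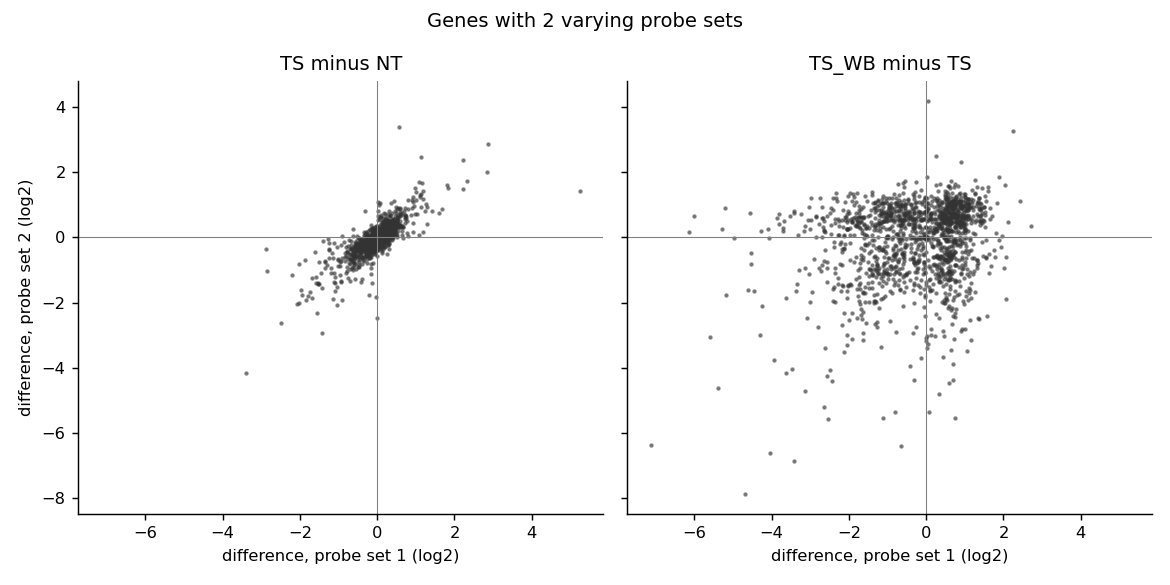
Log2 differences of 2 varying probe sets of the same gene plotted against each other for 1502 genes, TS minus NT on the left and TS_WB minus TS on the right; each point is a gene. The correlation is 0.80 on the left and 0.224 on the right.

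With that control difference of 5.69 on the TS_WB arrays, 10 lists shifted, all down, and none was called with an estimated correlation (lowest adjusted p = 0.203). With constant genes left out of camera's reference, 6 were called. In hyperproliferative and stress-induced epidermis 16 of 30 fell and none rose (the same adjusted over the list alone, median -0.99, adjusted p = 0.00341, adjusted p = 0.384 with an estimated correlation). Krt17 (-4.40, SE 0.19), Il1f9 (-3.69, SE 0.16) and Il1f8, interleukin 36 beta (-3.26, SE 0.18), fell. In desquamation proteases and inhibitors 16 of 28 fell and 6 rose (16 and 7 adjusted over the list alone, median -1.29, adjusted p = 0.000944, adjusted p = 0.203 with an estimated correlation). Cathepsin Ctsd fell by 4.63 (SE 0.12) and Klk8 fell by 3.17 (SE 0.17). In late differentiation and cornified envelope 16 of 42 fell and 12 rose (17 and 12 adjusted over the list alone, median -0.30, adjusted p = 0.0493, adjusted p = 0.683 with an estimated correlation). Cnfn, which encodes cornifelin, fell by 3.45 (SE 0.19) and Asprv1 fell by 2.47 (SE 0.17), while Flg rose by 0.61 (SE 0.16). This call rested on small margins: it was lost without NT 1 (adjusted p = 0.0510), NT 2 (0.0514), NT 3 (0.0510), NT 5 (0.0506), TS 2 (0.0518), TS 3 (0.0618), TS 6 (0.0523), TS_WB 1 (0.0585) or TS_WB 3 (0.0527), and with the filter on dim probe sets (0.105). It was also lost in a fit of the 12 arrays alone (adjusted p = 0.0527), with the mean of a gene's probe sets (0.0721) and among varying genes alone (0.218). Krt1 (0.00, SE 0.17), Krt10 (0.13, SE 0.09) and Lor (0.37, SE 0.23) did not pass; after quantile normalization they differed by 0.40, 0.81 and 0.84 and passed (adjusted p = 0.0272, 4.2e-06 and 0.00343).

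Sprr1b fell by 1.18 (SE 0.46, adjusted p = 0.0482). It did not pass without any 1 of the 6 NT arrays (adjusted p = 0.0507 to 0.0585), nor without TS 1 (0.0746), TS 2 (0.105), TS 3 (0.0749), TS 5 (0.0980), TS_WB 1 (0.0812), TS_WB 2 (0.109), TS_WB 5 (0.0594) or TS_WB 6 (0.115). Quantile normalization (adjusted p = 0.103), a trended prior (0.0540) and a fit of the 12 arrays alone (0.0988) also ended it. Klk7 fell by 1.46 (SE 0.05), and Ivl (-0.30, SE 0.12, adjusted p = 0.0530), Mki67 (0.42, SE 0.24) and Tslp (0.24, SE 0.21) did not pass. Ivl passed after median centring (adjusted p = 0.0413), among varying probe sets alone (0.0222) and without TS 1 (0.0481), TS 5 (0.0360) or TS_WB 5 (0.0481). Mki67 passed after quantile normalization (adjusted p = 0.0461) and without TS_WB 6 (0.0380). The basal keratins Krt5 and Krt14 fell by 3.20 (SE 0.23) and 2.88 (SE 0.18). On the deposited values the basal keratinocyte list was not called by camera (5 rose and 7 fell of 18, the same adjusted over the list alone, adjusted p = 0.188), while fry called it down (adjusted p = 1.0e-05). After quantile normalization and median centring, which shift the constant genes that camera sets it against, camera called it down too (adjusted p = 0.000372 and 0.000211).

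Immune lists on these arrays, with the Gapdh 3' minus 5' difference at 3.70 against -0.44 in TS, shifted down in 4 cases. In inflammatory cytokines and chemokines 14 of 37 fell and none rose (the same adjusted over the list alone, median -0.86, adjusted p = 0.0238, adjusted p = 0.203 with an estimated correlation), including Ccl6 (-3.01, SE 0.24), the receptor antagonist Il1rn (-1.96, SE 0.12) and Il1b, which fell from 8.14 ± 0.68 to 7.14 ± 0.23. Another probe set of Ccl6 changed by 0.26 without passing, and another of Il1rn by -1.75. In Langerhans and dendritic cells 11 of 24 fell and 1 rose (the same adjusted over the list alone, median -1.73, adjusted p = 0.00625, adjusted p = 0.203 with an estimated correlation). The invariant chain Cd74 (-2.94, SE 0.21) and Cd207 (-2.12, SE 0.20) fell. In macrophages and monocytes 16 of 33 fell and 6 rose (17 and 8 adjusted over the list alone, adjusted p = 0.0271, adjusted p = 0.657 with an estimated correlation). Lysozyme Lyz2 (-3.51, SE 0.13) and Cd68 (-3.69, SE 0.24) fell. In mast cells 9 of 18 fell and 2 rose (the same adjusted over the list alone, median -1.60, adjusted p = 0.0122, adjusted p = 0.334 with an estimated correlation). The chymases Mcpt4 (-4.21, SE 0.16) and Cma1 (-3.20, SE 0.15) fell. Among varying genes alone, the macrophage and mast cell lists were not called (adjusted p = 0.112 and 0.0585). S100a9 fell by 3.33 (SE 0.82, adjusted p = 0.00315) and S100a8 did not pass (-0.48, SE 0.81).

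Beside the actin control difference of 5.69, antioxidant and NRF2 targets held 15 of 31 that fell and 8 that rose (the same adjusted over the list alone, adjusted p = 0.0328, adjusted p = 0.203 with an estimated correlation), with heme oxygenase Hmox1 at -3.56 (SE 0.13) and Taldo1 at -2.78 (SE 0.10). The antioxidant call was lost with the filter on dim probe sets (adjusted p = 0.103) and among varying genes alone (0.169). In skeletal muscle 27 of 41 fell and 2 rose (27 and 3 adjusted over the list alone, median -1.53, adjusted p = 5.6e-06, adjusted p = 0.384 with an estimated correlation). Skeletal actin Acta1 (-3.84, SE 0.19) and the myosin light chain Mylpf (-5.66, SE 0.22) fell. In adipocytes 15 of 24 fell and 3 rose (the same adjusted over the list alone, median -0.95, adjusted p = 0.000944, adjusted p = 0.206 with an estimated correlation), with Orm1 at -4.35 (SE 0.29) and resistin (Retn) at -2.30 (SE 0.17). Of 51 hair follicle genes 16 rose and 4 fell (17 and 4 adjusted over the list alone, median 0.36), but the list was not called (adjusted p = 0.366).

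In all, 21055 probe sets passed in TS_WB against TS, 12668 higher and 8387 lower. Of these 10612 differed by at least 0.01, which is 88.8% of the 11946 varying probe sets, and 7403 by at least 1.5-fold (3558 higher and 3845 lower). The group comparison and the control probe set difference coincide array by array, so the 6 TS_WB arrays give no estimate of an extract effect apart from it.

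The design also asks whether changes made by stripping went the other way with the extract. Of probe sets that passed in TS against NT, 53.3% had the opposite sign in TS_WB against TS, and 44.8% of the 4551 that differed by at least 0.01. Independent signs would give 50.1% of the latter. The TS arrays enter both comparisons, and unchanged groups simulated with shared TS arrays gave 78.7% (77.4 to 80%). Those groups hold no true differences, and their 2 sets of differences correlated at -0.50, against 0.01 in the data. The simulated share is therefore no reference for probe sets that stripping changed, and reversal is not judged by it. With the TS arrays split 3 and 3, so that no array entered both comparisons, 45.8% were opposite on average over 20 splits (44.2 to 47.2%). For all probe sets that passed, rounding differences included, the splits gave 51.5% (49.2 to 53.1%), just below the 53.3% above. The covariance of the differences was 0.00900, against -0.0118 in the simulation and 0.0185 on average in the splits. Krt16 (4.52, then -5.40), Tgm1 (1.23, then -1.89) and Il1f9 (1.75, then -3.69) passed in opposite directions, while Flg (1.05, then 0.61) passed upward in both. None of these genes has a further varying probe set, and the actin 3' minus 5' difference was 0.16 in TS and 5.69 in TS_WB. Their second differences therefore cannot be told apart from that control difference and do not show a reversal by the extract.

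The comparison of TS_WB with NT asked how far stripped skin of extract-fed mice stood from unstripped skin, again beside an actin 3' minus 5' difference of 5.69 in TS_WB and -0.51 in NT. Rptn was higher by 9.14 (SE 0.32, adjusted p = 9.2e-13, n = 6 per group), from 5.09 ± 0.62 to 14.23 ± 0.55, and Krt6b by 7.08 (SE 0.42). Krt77 fell from 15.10 ± 0.23 to 6.11 ± 0.48, below the median of the TS_WB arrays (adjusted p = 2.4e-14). Muscle transcripts were far lower, with Pvalb at -8.02 (SE 0.36) and creatine kinase Ckm at -6.62 (SE 0.33). Flg (1.66, SE 0.16), Krt1 (1.34, SE 0.17), Lor (0.89, SE 0.23) and Mki67 (1.26, SE 0.24) rose, and Krt5 (-2.50, SE 0.23) and Krt14 (-2.19, SE 0.18) fell.

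Further large rises were those of Klk13 (5.79, SE 0.33), Sprr2d (5.32, SE 0.35), Ereg (4.57, SE 0.26), Depp1 (4.44, SE 0.35), the late envelope gene Lce3f (4.29, SE 0.50) and the muscle ubiquitin ligase Trim63 (4.23, SE 0.61). Krt16 (-0.88, SE 0.50, adjusted p = 0.172), Ivl (0.19, SE 0.12) and S100a8 (1.45, SE 0.81) did not pass. Ivl passed after quantile normalization (adjusted p = 0.0281), and S100a8 passed without NT 4 (0.0175). Krt6a fell by 0.93 (SE 0.30, adjusted p = 0.0190), and Tslp fell by 0.61 (SE 0.21, adjusted p = 0.0244), though not without NT 2 (0.0608), NT 3 (0.0513) or TS_WB 4 (0.0577), nor in a fit of the 12 arrays alone (0.0557). Sprr1b (3.91, SE 0.46) and Krt10 (0.68, SE 0.09) rose. Tgm1 (-0.66, SE 0.11), Klk7 (-1.22, SE 0.05), Il1b (-1.50, SE 0.27), Il1f9 (-1.93, SE 0.16) and Cd207 (-2.58, SE 0.20) fell, and S100a9 did not pass (-1.75, SE 0.82), except without TS_WB 3 (0.0493) and among varying probe sets alone (0.0447).

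Beside the same control difference, 12 lists shifted, all down, and none was called with an estimated correlation (lowest adjusted p = 0.0726). With constant genes left out of camera's reference, 6 were called. In skeletal muscle 34 of 41 fell and none rose (the same adjusted over the list alone, median -2.73, adjusted p = 1.1e-12, adjusted p = 0.205 with an estimated correlation), and in adipocytes 18 of 24 fell and none rose (19 and 0 adjusted over the list alone, median -1.31, adjusted p = 9.0e-08, adjusted p = 0.0726 with an estimated correlation), with Cidec at -5.34 (SE 0.26). In Langerhans and dendritic cells 12 of 24 fell and none rose (the same adjusted over the list alone, median -2.57, adjusted p = 5.2e-05, adjusted p = 0.0726 with an estimated correlation), such as H2-Ab1 (-2.74, SE 0.15). In macrophages and monocytes 20 of 33 fell and 1 rose (21 and 2 adjusted over the list alone, adjusted p = 2.5e-05, adjusted p = 0.454 with an estimated correlation). In inflammatory cytokines and chemokines 15 of 37 fell and 2 rose (the same adjusted over the list alone, median -1.50, adjusted p = 0.00970, adjusted p = 0.0726 with an estimated correlation), such as Ccl7 (-3.12, SE 0.18). In prostaglandin and leukotriene genes 12 of 27 fell and 2 rose (the same adjusted over the list alone, adjusted p = 0.00643, adjusted p = 0.0726 with an estimated correlation), such as Pla2g7 (-3.97, SE 0.32). In collagens and matrix 22 of 42 fell and 8 rose (the same adjusted over the list alone, adjusted p = 0.00970, adjusted p = 0.459 with an estimated correlation), such as lumican (Lum, -3.02, SE 0.08).

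With the actin control difference at 5.69, interferon response genes such as Ifi27 (-2.75, SE 0.14) held 11 of 32 that fell and none that rose (the same adjusted over the list alone, adjusted p = 0.00645, adjusted p = 0.459 with an estimated correlation), and T cell genes such as Cd3g (-2.38, SE 0.18) 6 of 27 that fell and none that rose (the same adjusted over the list alone, adjusted p = 0.00801, adjusted p = 0.0726 with an estimated correlation). Antioxidant and NRF2 targets held 16 of 31 that fell and 8 that rose (the same adjusted over the list alone, adjusted p = 0.00970, adjusted p = 0.110 with an estimated correlation). With the filter on dim probe sets the interferon, T cell and antioxidant lists were not called (adjusted p = 0.0797, 0.0797 and 0.0711), nor was the T cell list after quantile normalization (0.693) or median centring (0.659). Among varying genes alone the interferon, collagen, antioxidant and prostaglandin lists were not called (adjusted p = 0.107, 0.107, 0.136 and 0.0638). The sebaceous gland and fatty acid synthesis list (14 fell and 6 rose of 32, the same adjusted over the list alone, adjusted p = 0.0412, adjusted p = 0.583 with an estimated correlation) lost its call without NT 2 (0.0657), TS_WB 3 (0.0516) or TS_WB 4 (0.0643). The filter on dim probe sets (adjusted p = 0.0987), array weights (0.0515) and varying genes alone (0.219) also ended it. The type 2 list (9 fell and 2 rose of 30, the same adjusted over the list alone, adjusted p = 0.0487, adjusted p = 0.0913 with an estimated correlation) lost it without NT 1 (0.0530), NT 2 (0.0534), NT 3 (0.0515), NT 4 (0.0528), TS_WB 3 (0.0578), TS_WB 4 (0.0537) or TS_WB 6 (0.0688). It was also lost after quantile normalization (adjusted p = 0.0642) and median centring (0.116), with the filter on dim probe sets (0.158), a trended prior (0.0618) or array weights (0.0552), among varying genes alone (0.219) and with the mean of a gene's probe sets (0.170). In all, 21749 probe sets passed, 13010 higher and 8739 lower; 10667 of them differed by at least 0.01 and 7598 by at least 1.5-fold. Of 1502 genes with 2 varying probe sets, 1261 had both past the test, and their signs were opposite in 505 (40.0%).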

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

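The tests on the TS_WB arrays, on the liver transcripts of NT 5 and on muscle, fat and follicle transcripts were chosen after the result was seen; the outlying values come from a fixed test of the gap of the highest or lowest array in a group, which chance meets in about 1 of 20 groups.

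The TS_WB arrays stood apart from all others in the control probe sets, which the comparisons do not use. Their 3' minus 5' difference averaged 5.69 for beta-actin and 3.70 for Gapdh. The bio and cre spike-ins, which are hybridisation controls, averaged 11.61 against 10.79 in TS. In both beta-actin and Gapdh the signal fell more towards the 5' end. Beta-actin averaged 13.47 in TS and 13.49 in TS_WB at the 3' end, 13.37 and 9.54 in the middle, and 13.32 and 7.81 at the 5' end. For Gapdh these means were 13.19 and 9.52, 13.23 and 7.03, and 13.63 and 5.82. Loss of 5' sequence in the labelled RNA would give this gradient, but these controls showed the pattern first. For other transcripts that explanation stays open, since the other mouse controls could not test it: the 5' probe sets of transferrin receptor and pyruvate carboxylase are constant, the former's 3' minus 5' difference is 0.83 on all arrays, and the latter's mean, 0.64 in TS_WB against 1.58 in TS, follows its 3' probe set alone. The tables argue against an extract effect as the whole cause, since 2 probe sets of a gene correlated at 0.224 (0.158 to 0.288) in TS_WB against TS but at 0.80 in TS against NT. They also argue against array scaling as the whole cause, since quantile normalization left 7884 probe sets of at least 1.5-fold in TS_WB against TS and 1390 in TS against NT; the test first written, replaced after its result was seen, set 44002 calls against 7020 as deposited and shows nothing, since shifted constant probe sets fix the former. What the extract itself contributed stays open, because it coincides with the control difference on every array.

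On the array NT 5, transcripts of liver stood out: Alb at 19.04, Apoa1 at 15.79, Ttr at 14.18 and a mean of 11.42 over varying liver markers, with a mean correlation to its own group of 0.904. Liver RNA in that sample may be the cause, but its test did not decide: 75% of the 16 varying markers of a fixed list of 30 (12 genes) were higher on NT 5 than on each of the other 17 arrays, where at least 80% had been asked for. The other 4, Hp, Cyp2e1, Hal and Cyp2f2, averaged 10.67 to 13.32 on the other NT arrays, levels that could hide liver RNA; a division of the markers by that level, made after this result was seen, leaves 12 of 12 higher. A liver sample in place of skin is argued against, since late differentiation genes on NT 5 lay 0.22 above the mean of the other NT arrays in the median. Of the 30 markers, 2 are also in the lists of skin genes, and no biological explanation was tested.

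Muscle, fat and follicle transcripts were lower in TS than in NT. A thicker epidermis diluting all deeper tissue alike is argued against as the whole cause. The median of muscle genes lay further down than that of endothelial genes, by -1.62 (-1.95 to -1.17, resampling genes). Genes of a tissue are not independent replicates, so this interval does not carry the spread between mice. Over arrays, varying muscle genes averaged 11.21 ± 0.46 in NT and 9.63 ± 0.20 in TS. Endothelial genes averaged 8.30 ± 0.10 and 8.39 ± 0.12. Dilution together with a rise of endothelial transcripts would also give this gap, and it was not tested. Less tissue from below the dermis in the TS samples cannot be told apart from a change within the tissue: over 12 arrays, each minus its group mean, muscle and fat scores had r = 0.0824 (permutation p = 0.852) and rho = 0.10 (permutation p = 0.773; 0.852 for both adjusted over the pair), and r = 0.27 without the 2 arrays farthest from the median; within NT r was 0.22 and within TS -0.27, and what r these arrays could detect was not tested. An effect of stripping on these tissues also stays open and was not tested.

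In all, 34 values, 28 of genes and the others of array measures, lay apart from their group, among 576 groups of 6 values tested, where chance gives 28.8. NT 5 held 7 of them: besides those above, Cidea at 11.02 was low and Apoc1 at 13.26 was high. TS 5 held another 7, all low: Calm4 (13.33), Krt1 (13.50), Flg (11.71), Lor (12.43), Ccl22 (6.97), Il1f8 (9.44) and Apoc1 (11.68). TS_WB 4 held Jup (10.17), Lpl (12.46), Fabp4 (10.27) and Trim63 (13.17), and TS_WB 3 held Ereg (10.89), Tpsb2 (7.27), Ivl (8.32) and Krt17 (8.74). NT 2 held Scd1 (13.74), Fasn (12.08) and Retn (11.95). The others were Rptn (13.16) and Stfa3 (12.49) on TS_WB 6, S100a8 on NT 4 (12.03), Ivl (9.54) and Rab32 (7.81) on TS 6, Cxcl3 (5.39) and Ssr4 (12.36) on TS 4, Klk8 on TS_WB 1 (8.40), and a Gapdh 3' minus 5' difference of 4.41 on TS_WB 2.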

How the results depend on the processing

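Alternatives restricted to varying probe sets or genes, or to differences of at least 0.01, were chosen after seeing the data. No named gene that passed and no called list changed its direction under any alternative run, but 4 lists that point up without a camera call were called down after scaling. In TS_WB against NT these were late differentiation and hyperproliferative epidermis (both scalings) and cell cycle (median centring), and in TS_WB against TS immediate early genes (median centring). Fry called hyperproliferative epidermis up in TS_WB against NT (adjusted p = 0.0124), opposite to the calls after scaling. Scaling raised the counts of the TS_WB comparisons: quantile normalization gave 44002 probe sets in TS_WB against TS and 43948 in TS_WB against NT (89.3% and 89.0% higher, where the values as deposited gave 60.2% and 59.8%), and median centring gave 43994 and 43993 (88.8% and 88.3% higher). By construction, aligning arrays whose medians differ by 0.036 and 0.039 shifts the constant probe sets, which then pass. The same shift enters the list tests, since only 6843 of the 18201 genes vary and camera compares a list with all others. A list of varying genes can thus be called down after scaling without a fall of its own. Rounding differences of constant genes can enter camera's reference on the deposited values too. There 60.2% of passing probe sets were higher in TS_WB against TS, but 53.1% of those that differed by at least 0.01. In TS_WB against NT these shares were 59.8% and 51.2%. The down calls of both comparisons are therefore read with their counts among varying genes alone. In TS against NT quantile normalization gave 68.8% higher calls where the deposited values gave 49.0%, and median centring 4316 calls. List counts rose to 19 in both TS_WB comparisons after quantile normalization and to 20 in both after median centring. The opposite share of 53.3% became 30.2% and 44.6%; the cause was not tested.

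Testing or counting fewer probe sets lowered the counts by construction. The filter on dim probe sets gave 10432 and 10469 in TS_WB against TS and NT, an opposite share of 45.5% and 7 lists in TS_WB against NT. Varying probe sets alone gave 10705 and 10750, and varying genes 6 and 6 lists. Differences of at least 0.01 numbered 4551, 10612 and 10667 in the 3 comparisons, with a share of 44.8%, and those of at least 1.5-fold 1417, 7403 and 7598. An adjusted p threshold of 0.01 left 4221 in TS against NT. The trended robust prior gave a share of 49.9%; the cause was not tested. With an estimated correlation 6, 0 and 0 lists were called, and with fry 28 and 23 in TS_WB against TS and NT, since fry compares a list with no other genes.

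Leaving out each array gave 6102 to 7224, 19835 to 21005 and 20334 to 21806 probe sets, 21 to 24, 9 to 13 and 10 to 12 lists, and an opposite share of 51.6 to 54.1%. Over these fits, 12 calls of named genes in TS against NT were lost and 7 gained, 14 and 4 in TS_WB against TS, and 3 and 2 in TS_WB against NT; list calls lost and gained numbered 3 and 8, 9 and 11, and 10 and 0. The replicate block gave 6329, 20338 and 21130 probe sets, 22, 9 and 11 lists and a share of 52.5%. Same-numbered arrays of NT and TS correlated at -0.13 to 0.13 after removal of group means, and 2 of 6 correlated best with their own number. For TS and TS_WB these values were -0.27 to 0.05 and 0 of 6, and for NT and TS_WB -0.05 to 0.14 and 2 of 6. No pairing by number was detected, but 6 weak correlations cannot exclude a shared cage or day. Under the block the late differentiation list in TS_WB against TS (adjusted p = 0.0523) and the type 2 list in TS_WB against NT (0.0511) were not called. Pmel in TS against NT (0.0592) and Sprr1b in TS_WB against TS (0.0672) did not pass, and Ivl in TS_WB against TS did (0.0381). The constant values are no floor, since Hr is constant at 7.46 while Rptn averages 5.09 in NT. What dim probe sets can show is limited by the lack of a background measure.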

Other observations

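The circadian clock list was not called by camera in stripped skin (3 rose and 4 fell of 19, 4 and 6 adjusted over the list alone, adjusted p = 0.214), while fry called it down (adjusted p = 0.0363). The clock output gene Dbp fell by 2.62 (SE 0.30, adjusted p = 3.7e-05, n = 6 per group), Per3 changed by -1.25 (SE 0.16) and Tef by -0.58 (SE 0.07), while Arntl, the activator of the loop, rose by 0.35 (SE 0.08). These genes and those of the next sentences were chosen after their values were seen. Metallothionein Mt4, of differentiating epithelium, rose by 2.09 (SE 0.24), and the beta-defensin Defb3 by 2.63 (SE 0.53) within an antimicrobial list that camera did not call (4 rose and 2 fell of 20, the same adjusted over the list alone, adjusted p = 0.0992). Fry called that list up (adjusted p = 0.000101). The antimicrobial list was called up with the filter on dim probe sets (adjusted p = 0.0263) and without NT 4 (0.0301). Melanocyte genes, in an albino strain, shifted up (3 rose and 1 fell of 14, 4 and 1 adjusted over the list alone, adjusted p = 0.0146, adjusted p = 0.0651 with an estimated correlation), with Tyrp1 at 1.36 (SE 0.30). That call was lost after quantile normalization (adjusted p = 0.511), median centring (0.401), the filter on dim probe sets (0.268) and among varying genes alone (0.299). Pmel rose by 0.56 (SE 0.17, adjusted p = 0.0361), but not without NT 1 (0.0783), NT 2 (0.0785), NT 4 (0.0863), TS 2 (0.0641), TS 3 (0.0765), TS 5 (0.0620) or TS 6 (0.0812), nor in a fit of the 12 arrays alone (0.0648).

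Camera did not call the remaining lists in TS against NT: neutrophils (2 rose and 2 fell of 23, the same adjusted over the list alone, adjusted p = 0.819), collagens and matrix (7 and 8 of 42, 7 and 9 over the list alone, 0.0944), matrix-degrading enzymes (3 and 3 of 29, 3 and 5, 0.724), endothelium (3 and 1 of 25, the same, 0.0638), Schwann cells and nerve (0 and 3 of 17, 1 and 3, 0.188) and red blood cells (0 and 2 of 9, the same, 0.356). Fry called collagens (adjusted p = 0.0383), nerve (0.0379) and red blood cells (0.0415) down and endothelium (0.0326) up, but not neutrophils or matrix-degrading enzymes. Collagens and matrix were called down after quantile normalization (adjusted p = 0.0258) and median centring (0.00406), in a fit of the 12 arrays alone (0.0322) and without NT 2 (0.0335) or TS 5 (0.0193). Endothelium was called up with array weights (adjusted p = 0.0427) and without NT 1 (0.0486), NT 2 (0.0204), TS 1 (0.0269), TS 2 (0.0428) or TS 6 (0.0485).

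In TS_WB against TS, beside the actin control difference of 5.69, camera did not call the lists not named so far with the values as deposited, with adjusted p = 0.0554 for antimicrobial proteins, 0.0571 for cell cycle and 0.0580 for endothelium as the lowest. On the same values fry called 28 of the 32 lists, with antimicrobial proteins (adjusted p = 7.8e-09), cell cycle (0.0210) and endothelium (1.3e-05) down. Antimicrobial proteins were called down after quantile normalization (adjusted p = 0.000114) and median centring (9.1e-05), with a trended prior (0.0441) or array weights (0.0445), and without NT 4 (0.0492), TS 1 (0.0476), TS 4 (0.0491) or TS_WB 4 (0.0472). Cell cycle was called down after quantile normalization (adjusted p = 2.5e-05) and median centring (7.2e-06), with a trended prior (0.0441) or the mean of a gene's probe sets (0.0245). It was also called without TS 3 (adjusted p = 0.0320), TS 4 (0.0162), TS 6 (0.0341), TS_WB 3 (0.0342) or TS_WB 4 (0.0287), and endothelium without TS 1 (0.0480) or TS_WB 4 (0.0462). After quantile normalization and median centring, ceramides (adjusted p = 6.1e-05 and 2.1e-05), cholesterol synthesis (0.00866 and 0.00678), collagens and matrix (6.3e-06 and 4.5e-07), matrix-degrading enzymes (0.0239 and 0.0168) and the sebaceous list (0.000209 and 9.7e-05) were called down too, as was the prostaglandin list (0.00678 after median centring). Fry called each of them down on the deposited values. The camera calls after scaling are set against shifted constant genes and are not read as falls. Immediate early genes, which camera points up without a call on the deposited values, were called down after median centring (adjusted p = 0.0370), and with the mean of a gene's probe sets collagens (0.0225) and prostaglandin genes (0.0340) were called down.

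In TS_WB against NT, with the same control difference, lists that camera did not call as deposited were called down after quantile normalization and median centring: antimicrobial proteins (adjusted p = 0.00501 and 0.00266), basal keratinocyte (0.0128 and 0.00740), ceramides (0.00547 and 0.00211), desquamation (6.6e-06 and 4.5e-06), hair follicle (0.000207 and 4.1e-05), mast cells (0.00380 and 0.00538) and matrix-degrading enzymes (0.0449 and 0.0294). These calls are set against constant genes that scaling shifted, so they are not read as falls. On the deposited values fry called antimicrobial proteins (adjusted p = 4.4e-06), desquamation (8.7e-06), mast cells (2.0e-06) and matrix-degrading enzymes (0.000123) down. It did not call basal keratinocyte, ceramides or hair follicle. Late differentiation (adjusted p = 0.000406 and 3.9e-05) and hyperproliferative epidermis (0.00603 and 0.00602) were also called down there, although camera points up without a call on the deposited values, and fry calls hyperproliferative epidermis up on them (adjusted p = 0.0124). Cell cycle, which camera also points up without a call, was called down after median centring (adjusted p = 0.0283). Hair follicle was also called in a fit of the 12 arrays alone (adjusted p = 0.0386).

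How often other splits of the same 12 arrays gave as much was counted with 100 of 462 splits drawn per comparison and the real one included. Chance is argued against at the 5% level for the numbers of probe sets, where 1 of 100 splits, the real one, reached the count in each comparison: 7020 in TS against NT with 513 as the highest other, 21055 in TS_WB against TS with 12215, and 21749 in TS_WB against NT with 12531. These counts include differences at the level of rounding, and splits were not counted for differences of at least 0.01. For TS_WB the splits cannot tell the extract from the control difference, which the whole group shares. For lists, 2 of 100 splits reached the 22 of TS against NT, the highest other also giving 22, so chance is argued against at the 5% level but 1 other split did as much. It cannot be excluded for the number of lists in TS_WB against TS, where 28 of 100 splits gave at least 10 (highest other 15), nor in TS_WB against NT, where 21 of 100 gave at least 12 (highest other 16).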
